A study of Homo sapiens with 8 samples.

How the data were processed

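MicroRNA (miRNA) levels were measured in total RNA from DLD-1 and KM12C, 2 established human colon carcinoma lines, each in a form sensitive to 5-fluorouracil (5-FU) and a form resistant to it. 5-FU is a pyrimidine analogue that blocks thymidylate synthase. The design text gives RNA taken at the start (0 h) and after 72 h with 60 µM 5-FU. Total RNA was extracted with the miRNeasy kit and labelled with Cy3, per the labels' protocols. Each of the 8 samples was hybridised to 1 one-colour Agilent human miRNA array. All 8 arrays lay on 1 slide and were read in 1 scan, per the file headers, so no slide or scan could be compared with another.

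The deposited scanner files hold spot intensity on a linear scale. Per the file headers, Feature Extraction 9.5.3.1 subtracted a spatially smoothed background from each spot and applied no normalization between arrays (version 9.5 per the submitters' processing notes). The deposited intensity flags (0 or 1) for outlier spots, saturation and signal well above background were used as given. The deposited table of processed values equalled Feature Extraction's total gene signal of the same array in all 821 rows within 0.1%, so it is on a linear scale and not centred. Its column medians were 0.295, -0.0284 and -0.161 for the DLD-1 sensitive 0 h, resistant 0 h and sensitive 72 h arrays. They were -0.118, -0.121 and -2.22 for the same KM12C arrays. The library with conflicting time labels had 0.257 and the library labelled DLD-1 resistant 72 h had 0.112.

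Of 13737 spots per array, 12784 carried miRNA probes: 2421 probes for 799 miRNAs, of which 723 were human and 76 viral. A miRNA had 1 to 4 probes and a probe 3 to 16 spots. Control spots and outlier spots were left out, and no miRNA spot was saturated. A probe counted as detected on an array when at least 50% of its spots were well above background. At most 13.3% of probes were detected on an array. Each array was therefore scaled to its 75th percentile over the 125 probes detected on all 6 arrays of the fit. A floor of 0.0758 (log2 -3.72) was then applied, the highest among the 6 arrays of the lowest scaled signal well above background. Values were taken to log2 and spots averaged on that scale. A miRNA was the mean of its probes detected on at least 2 of the 6 arrays, which kept 266 probes and 152 miRNAs (150 human, 2 viral). miRNAs at the floor on all arrays of a group have only a bound there. Where no array of the dim group detected the miRNA, the difference is given as "at least N-fold", the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the miRNA's own signal.

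Labels of 6 arrays were free of conflict: sensitive 0 h, resistant 0 h and sensitive 72 h of each line. The remaining 2 were kept out of the tests. For the first, the source name gave DLD-1 resistant 72 h and the time tag gave 0 h. The second carried DLD-1 resistant 72 h in every label, while the design text has a KM12C resistant 72 h sample that no label names. It is called the library labelled DLD-1 resistant 72 h throughout. Each was set against the DLD-1 resistant 0 h array and never averaged with the other.

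With 1 array per group, the 2 lines served as the replicates of the other contrasts. limma 3.58.1 in R 4.3.3 (data.table version 1.17.8) fitted line, status and time together on 6 arrays, leaving 2 residual degrees of freedom with a prior of 0.502. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over 152 miRNAs, for 3 contrasts: resistant against sensitive at 0 h, 72 h against 0 h in sensitive cells, and KM12C against DLD-1. No source used here says whether samples came from separate cultures. The 2 residual degrees of freedom hold how far the status and time effects differ between the 2 lines, which may be technical. The p-values are set against that difference and measure no spread between replicates. Differences between 2 single arrays have no replicate check, and their standard error over spots is technical. In 50 simulated draws with 30 of 152 miRNAs changed, a log2 change of 1 was recovered in 72.0% of cases for resistance, 68.8% over 72 h and 76.5% between lines. The false share of calls was 6.83%, 7.40% and 6.58%, slightly above the nominal 5%. The draws used each miRNA's fitted spread, also for miRNAs at the floor, and applied no floor. Changing 30 miRNAs by log2 1 or 2 also eases the adjusted threshold. The recovered shares may thus be too high for these data, and a count of 0 calls does not show that nothing changed.

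Before the data were examined, 24 miRNA lists were fixed: the miR-17/miR-92 and paralogous clusters; p53-responsive; let-7, miR-200, miR-15/16, miR-29, miR-30, miR-181 and miR-221/miR-222 families; miR-23/24/27, miR-183, miR-302/miR-372, chromosome 19 and chromosome 14 clusters; intestinal epithelium, colorectal tumour, hypoxia and DNA damage lists; haematopoietic, muscle, liver, neural and fibroblast markers; and viral probes. Older names were matched to the array's names after the arrays were seen. The 12 lists with at least 3 tested members were tested with limma's camera at an inter-gene correlation of 0.01. In the simulations a list of 14 miRNAs shifted by -0.5 was called in 100% of draws, and an unshifted one in 6%, 8% and 6% for the 3 contrasts. These lists were drawn at random with independent noise and called at an unadjusted p under 0.05. The shares therefore say nothing about lists whose members vary together, such as miRNAs of 1 cluster, or about smaller shifts.

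The rule for named miRNAs was also fixed then. For each contrast it takes every tested member of the miR-17/miR-92 list and the 10 called miRNAs with the highest and the 10 with the lowest mean change. Where fewer than 10 pass, miRNAs that moved at least 1.5-fold the same way in each pair fill up, as values without a call. From the lists it takes 2 to 4 members with the widest change, and the lower number was used here. miRNAs outside it were chosen after their values were seen and are pointed out.

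Alternatives set beforehand were normexp background correction (offset 50), 3 other scalings, 2 other detection filters, the brightest probe, total gene signal, 2 other variance estimates, fits on the arrays of 1 comparison or without line, adding each doubtful library, and leaving out each library. Cyclic loess, the lowest floor, leaving out miRNAs at the floor throughout, and list tests under all scalings but quantile normalization were added after the data were seen. Coordinates are those printed in the array files, whose genome build is not given in the sources used here. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.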

Results

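The series set out to relate miR-19b to 5-FU resistance in colon cancer cells. The 8 arrays, 1 per labelled sample, covered DLD-1 and KM12C cells, sensitive or resistant to the drug. Signal differed between arrays: the 75th percentile of signal over commonly detected probes was 122.9 on the DLD-1 sensitive 0 h array, 150.0 on the resistant 0 h array and 300.9 on the sensitive 72 h array. The same KM12C arrays had 273.5, 277.7 and 420.7. The number of miRNAs detected was 100, 125 and 134 in DLD-1 and 138, 135 and 111 in KM12C. The DLD-1 sensitive 0 h array had the fewest spots well above background and the highest limit after scaling, which set the floor. The KM12C sensitive 72 h array had the most spots at or below 0 (58.3%) and the highest limit before scaling (26.1, against 6.18 to 11.4 on the other 5). The median spread between spots of one probe was 6.09% to 9.37% of the signal. One array per group limits the precision of every value.

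Marker lists of other cell types gave almost no signal. None of the 7 haematopoietic, 5 muscle and 1 liver markers on the array was detected in any library, nor were the 8 members of the miR-302/miR-372 cluster or the 14 of the chromosome 19 cluster. One of 7 neural markers, 1 of 7 fibroblast markers and 1 of 21 chromosome 14 cluster members were tested, and none was called in any contrast. The fibroblast marker was miR-10b, which lies in the HOXD cluster. It belongs to the same family as miR-10a, which DLD-1 expressed strongly, but miR-10b itself differed by only log2 -0.15 between KM12C and DLD-1.

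KM12C and DLD-1 were first compared across 3 matched conditions, to describe the background on which the drug was tested. miR-10a, encoded in the HOXB cluster, showed the widest gap and was 47.3-fold lower in KM12C, at log2 -3.45 ± 0.24 (SD, n = 3) against 2.11 ± 0.17 in DLD-1. The fold is partly set by the floor, which the KM12C sensitive 0 h array nearly reached. miR-886-3p, now usually described as a fragment of a vault-like RNA, was not detected in KM12C, at log2 -3.73 against the floor and at least 27-fold lower against the KM12C arrays' own limits. In the other direction miR-192 and miR-215, typical of intestinal epithelium and induced by p53, were higher in KM12C, miR-192 by 17.2-fold and miR-215 at 14.5-fold above the floor, where all 3 DLD-1 arrays stood. miR-31, often raised in colorectal tumours, was 6.02-fold higher, with DLD-1 close to the floor. Each of these differences had the same direction in 3 of 3 matched pairs.

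limma called 27 of 152 miRNAs between the lines, 13 higher and 14 lower in KM12C. miR-10a differed by log2 -5.56 (SE 0.04, adjusted p = 7.2e-04). The passenger strand miR-10a* (-1.37, adjusted p = 0.0063) and miR-149 (-1.17, adjusted p = 0.0020) were lower, with all 3 KM12C arrays at the floor and none detecting them. Against the KM12C arrays' own limits, which lie below the floor, they were at least 5.27-fold and 4.57-fold lower. miR-221, a repressor of the cell cycle inhibitor p27, was 5.10-fold lower (adjusted p = 0.0023), and miR-196b of the HOXA cluster was 3.40-fold lower. Smaller falls below DLD-1 were called for miR-23a (-0.86), miR-140-3p (-0.79), miR-331-3p (-0.75), miR-197 (-0.68) and miR-93 (-0.62). Higher in KM12C were miR-192 at log2 4.10 (SE 0.34, adjusted p = 0.0271) and miR-215 at 3.86 (SE 0.45, adjusted p = 0.0425). Their partner miR-194, also at the floor on all 3 DLD-1 arrays, lay 2.46 above it in KM12C in 3 of 3 pairs and missed the threshold (adjusted p = 0.0726). The fitted values of miR-194 and miR-215 are limited by the floor. miR-194 was named after its values were seen.

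All 5 tested miR-30 members were higher in KM12C in 3 of 3 pairs, with a median of 0.70, and the family passed camera (adjusted p = 0.0045). With an estimated correlation it did not (adjusted p = 0.788), nor under normexp (adjusted p = 0.261) or scaling over all probes (adjusted p = 0.102). miR-30b was 4.04-fold and miR-30d 3.20-fold higher. Both are called, and 4 members pass when adjusted over the list alone. In DLD-1, miR-30b stood close to the floor, at -3.55 and -3.51 in sensitive and resistant cells at 0 h and -3.42 at 72 h. Of the 7 members on the array, 2, 4 and 5 were detected on the same DLD-1 arrays. The direction counts, the 4.04-fold value and the spread behind these calls are thus partly set by the floor. Of the 5 members of the miR-23/24/27 clusters, 4 were called and 5 when adjusted over the list alone, in opposite directions: miR-23b (2.27) and miR-27b (2.08), neighbours on chromosome 9, were higher in KM12C, while miR-23a was lower. miR-24, made from both clusters and named after its values were seen, differed by 0.13. miR-16 (0.65) and miR-15a (0.60), which repress BCL2, were called higher, 2 of 4 in their family over either set. miR-7 was 1.08 higher.

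Of the 10 intestinal epithelium miRNAs, 4 were called higher and 1 lower in KM12C, and 7 when adjusted over the list alone. The p53-responsive list had 2 of 5 called higher and 3 over the list alone, with camera at adjusted p = 0.0901. That list was called higher under normexp, scaling over all probes and total gene signal (adjusted p = 6.3e-06, 0.0182 and 0.0280), but not with an estimated correlation (adjusted p = 0.557, 0.935 and 0.984). The DNA damage list had 2 higher and 1 lower of 6 (3 over the list alone), led in size by miR-29b at -1.20, which was not called. The colorectal tumour list had 1 of 8 higher, miR-31, and 1 over the list alone. One of 2 miR-221/miR-222 members was lower (2 over the list alone), as was the single hypoxia miRNA, miR-210, at -0.28 with all 3 KM12C arrays at the floor, named after its values were seen. No member of the let-7 (9 tested), miR-200 (6), miR-29 (3), miR-181 (2) and miR-183 (3) lists was called over all miRNAs. Over the list alone 1 miR-183 member and the 1 fibroblast marker passed. let-7e differed by 0.90, let-7g by 0.67, miR-200a by 1.15, miR-429 by 0.68, miR-29a by -0.62, miR-183 by -1.16 and miR-96 by -0.07. In the miR-17/miR-92 list 1 of 14 was called, miR-93, and 1 over the list alone. miR-19b was at 0.53 (adjusted p = 0.194), miR-92a at -0.37 (adjusted p = 0.130) and the other 11 between -0.25 and 0.31. Median, mean and test did not share a sign for the miR-17/miR-92, let-7, colorectal tumour and DNA damage lists.

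Adding the library labelled DLD-1 resistant 72 h under its label ended all 27 calls. Scaling over all probes gave 4 calls, 3 of them among the 27, and the fit without a detection filter kept 2. Other settings called more: 102 under normexp (13 higher, 89 lower), 73 with total gene signal, 46 over probes detected on all 6 arrays, 44 with the library with conflicting time labels as 0 h, 74 with the lowest floor, 43 without miRNAs at the floor and 42 after cyclic loess. The normexp offset was added before scaling, which lowers dim miRNAs on brighter arrays. Each KM12C array was brighter than its DLD-1 match, so the excess of lower calls cannot be told apart from that shift. Leaving out 1 library, which leaves 1 residual degree of freedom, gave 8 calls without either sensitive 0 h array, 17 without either resistant 0 h array and 4 without either sensitive 72 h array.

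**Figure D1:**
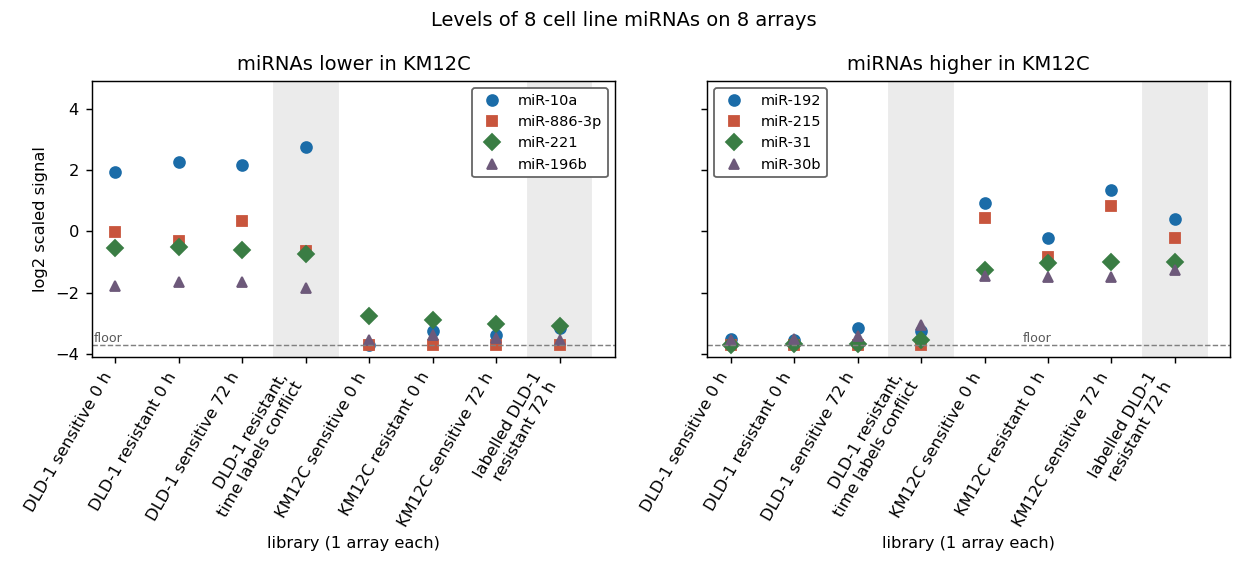
Log2 scaled signal (vertical axis) of 8 miRNAs called between the lines, for each of 8 arrays (horizontal axis); 1 point is 1 array, the dashed line marks the floor at -3.72, and grey bands mark the 2 libraries with doubtful labels. The library labelled DLD-1 resistant 72 h has miR-10a at -3.14 and miR-192 at 0.40, near the 3 KM12C arrays.

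The 2 libraries with doubtful labels were set against these levels. The library labelled DLD-1 resistant 72 h had miR-10a at -3.14, where the DLD-1 arrays had 1.93, 2.25 and 2.16 and the KM12C arrays had -3.71, -3.25 and -3.38. Its miR-192 level was 0.40, against -3.55 to -3.16 in DLD-1 and -0.22 to 1.36 in KM12C. Of the 27 miRNAs called between lines, 24 lay nearer the KM12C mean. Across 152 miRNAs, which are not independent replicates, it correlated with the KM12C arrays at r = 0.972 to 0.983 and with the DLD-1 arrays at 0.804 to 0.822. Taken as labelled, it had 15 miRNAs at least 2-fold above and 10 at least 2-fold below the DLD-1 resistant 0 h array among 143. Single-array comparisons of this kind have no replicate check. The library with conflicting time labels had miR-10a at 2.74 and miR-192 at -3.26. It correlated with DLD-1 at 0.974 to 0.986 and with KM12C at 0.787 to 0.829, and 3 of the 27 miRNAs lay nearer the KM12C mean. None of 136 miRNAs differed 2-fold from the DLD-1 resistant 0 h array, and 9 were at least 1.5-fold above and 2 below.

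Resistant and sensitive cells at 0 h were compared to ask which miRNAs go with resistance before the drug is added. No miRNA passed the test in both lines together. miR-19b, named in the study's title, was lower in resistant cells of both lines by a small margin, at -0.11 in DLD-1 and -0.25 in KM12C. The mean of -0.18 was within its standard error of 0.24 (adjusted p = 0.960, lower in 2 of 2 lines). It turned to 0.25 with the library with conflicting time labels as 72 h, to 0.07 with the library labelled DLD-1 resistant 72 h, and ranged from -0.39 to 0.03 on leaving out 1 library. Some of these leave-one-out fits also draw on the 72 h arrays, so the 0.03 is not a rise measured in either line. The widest differences were seen in KM12C: miR-192 was 2.20-fold, miR-194 2.26-fold and miR-215 2.43-fold lower in resistant KM12C, and let-7e was 2.21-fold higher. In DLD-1 these 4 differed by -0.03, 0.00, 0.00 and 0.01, with miR-194, miR-215 and let-7e at or close to the floor there and miR-192 not far above it, so DLD-1 could hardly show a fall of the 3. Whether the lines differ was not tested.

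limma called 0 of 152 miRNAs, with 5 at an unadjusted p under 0.05 where 7.6 would be expected by chance. These 5 were miR-10a (0.39, SE 0.04), miR-10b (0.25), miR-196b (0.14) and miR-151-5p (0.37), higher in resistant cells of both lines, and miR-16 (-0.21), lower in both. Each had adjusted p = 0.876, and all but miR-16 were named after their values were seen. In DLD-1, 0 of 120 miRNAs differed 2-fold between the 2 arrays. In KM12C 1 of 135 was at least 2-fold higher and 3 were lower, which are the 4 named above. At 1.5-fold the numbers were 1 higher and 4 lower in DLD-1, and 3 higher and 8 lower in KM12C, with 0 miRNAs shared in direction. The 5 in DLD-1 became 82 with scaling over all probes. That scale was 1.40 on the sensitive and 0.74 on the resistant array, below the SD of their negative controls (2.44 and 2.32). It thus follows background, and the 82 hold a shift of whole arrays.

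No list was called for resistance, and the lowest adjusted p was 0.275 for the miR-15/16 family, in which miR-15b was at -0.42 (-0.17 in DLD-1 and -0.66 in KM12C). Of the 14 tested miR-17/miR-92 members, 3 were lower in both lines and 2 higher, not counting miR-18a at 0.00 in DLD-1. miR-19a was at -0.33 (-0.71 in DLD-1 and 0.06 in KM12C), miR-17* at -0.26 (SE 0.09, lower in 2 of 2 lines, adjusted p = 0.876) and the other 11 between -0.15 and 0.17. The p53-responsive list (5 tested, median -0.59) and the intestinal list (10 tested, median -0.16) were led by miR-215 at -0.64 and miR-194 at -0.59. miR-192, at -0.59, was named after its values were seen. Among the other lists, the widest values were let-7e 0.58 and miR-98 0.28 for let-7, miR-200a -0.24 and miR-141 0.24 for miR-200, miR-29c -0.10 and miR-29b -0.07 for miR-29, and miR-30e* 0.11 and miR-30d -0.09 for miR-30. They were miR-27a -0.17 and miR-23a -0.12 for miR-23/24/27, miR-183 0.29 and miR-96 0.22 for miR-183, and miR-21 -0.32 and miR-34a -0.31 for the DNA damage list. The colorectal tumour list was led by the same miR-21 and miR-183. When adjusted over the list alone, 0 members of any list passed except the single fibroblast marker, miR-10b. The 2 tested members of each of the miR-181 and miR-221/miR-222 families had medians of 0.11 and -0.16. Median, mean and test did not share a sign for miR-200, miR-23/24/27 and the intestinal list.

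Scaling to the median of detected probes called 1 miRNA for resistance, miR-221, lower at -0.18. Without the KM12C resistant 0 h array, the fitted differences of miR-194 and miR-215 were 0.12 and 0.10. Both stood at the floor on the DLD-1 sensitive and resistant 0 h arrays, so no rise was measured. That fit also draws on the 72 h arrays. Other settings called lists for resistance. The p53-responsive list was lower under normexp, scaling over all probes and total gene signal (adjusted p = 3.4e-07, 0.0016 and 0.0219). It was not called there with an estimated correlation (adjusted p = 0.453, 0.998 and 0.635). Under normexp let-7 was also higher (adjusted p = 0.0087) and the intestinal list lower (adjusted p = 0.0176), neither of them with an estimated correlation (adjusted p = 0.748 each). After cyclic loess the miR-17/miR-92 list and the miR-15/16 family were lower (adjusted p = 0.0200 each), but not with an estimated correlation (adjusted p = 0.624 each).

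**Figure D2:**
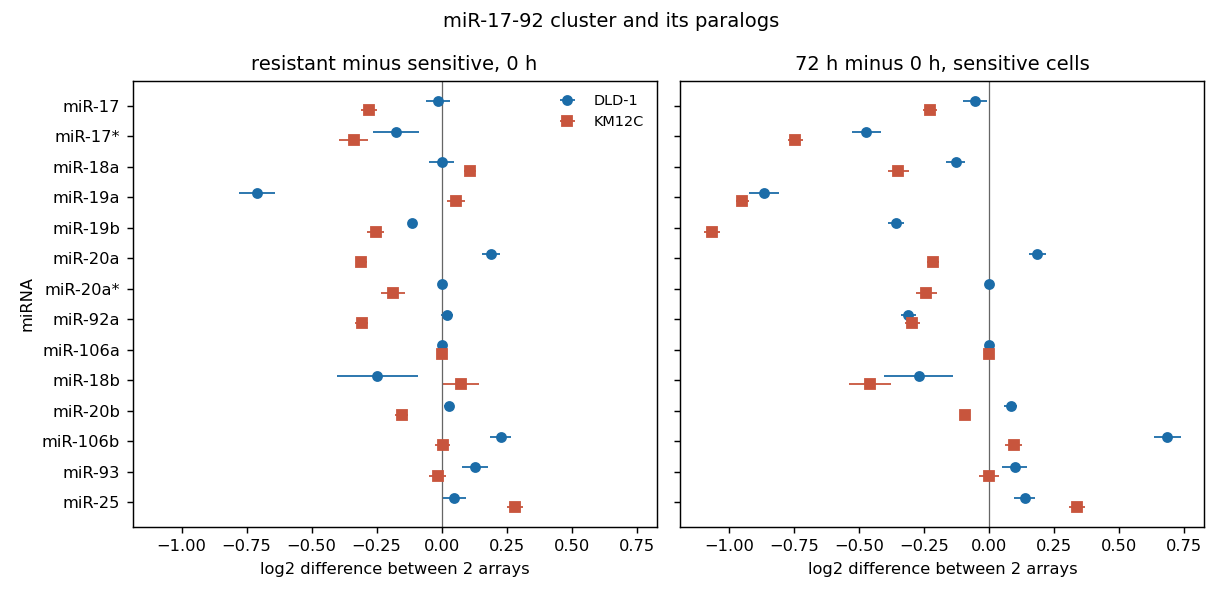
Log2 difference between 2 arrays (horizontal axis) for the 14 tested members of the miR-17/miR-92 list (vertical axis) in DLD-1 (circles) and KM12C (squares), resistant minus sensitive at 0 h (left) and 72 h minus 0 h in sensitive cells (right); bars are the standard error over spots, which is technical. miR-19b lies at -0.11 and -0.25 for resistance and at -0.36 and -1.07 over 72 h, and for resistance it is at 0.08 with scaling over all probes once the shift of all miRNAs (0.41) is removed.

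Sensitive cells at 72 h were compared with 0 h to ask which miRNAs move with 5-FU. In both lines, 5 miRNAs were at least 1.5-fold higher at 72 h and 1 was at least 1.5-fold lower. miR-34a, a direct target of p53, was 2.39-fold higher in DLD-1 and 1.82-fold higher in KM12C. miR-193b was 1.75-fold and 2.01-fold higher, miR-181a 1.78-fold and 1.73-fold, miR-181b 1.70-fold and 1.69-fold, and miR-197 1.57-fold in both. miR-19a, of the miR-17/miR-92 cluster, was 1.82-fold and 1.93-fold lower. On the KM12C 72 h array it was not above background, so its difference there is limited by the floor. miR-181b and miR-197 stood at or close to the floor on the KM12C 0 h array. miR-19b was 1.28-fold lower in DLD-1 and 2.09-fold lower in KM12C.

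limma called 0 of 152 miRNAs over 72 h, with 19 at an unadjusted p under 0.05 where 7.6 would be expected. The lowest adjusted p was 0.146, for miR-193b (0.91, SE 0.06) and miR-197 (0.65, SE 0.04), both higher in 2 of 2 lines. miR-34a was at 1.06 (SE 0.24, adjusted p = 0.275), miR-181a at 0.81 (adjusted p = 0.275), miR-181b at 0.76 (adjusted p = 0.174) and miR-19a at -0.91 (SE 0.30, adjusted p = 0.447). At 2-fold, DLD-1 had miR-34a and the viral ebv-miR-BART13 higher and miR-923 lower, of 134 miRNAs. KM12C had miR-193b higher and miR-19b lower, of 144. miR-923 went the other way in KM12C, at 0.40 against -1.41 in DLD-1. ebv-miR-BART13 and miR-923 were named after their values were seen. At 1.5-fold, 7 were higher and 10 lower in DLD-1, and 10 higher and 6 lower in KM12C. These 17 and 16 became 50 and 109 with scaling over all probes. That scale was 1.40 at 0 h and 2.35 at 72 h in DLD-1, and 0.84 and 4.18 in KM12C. The SD of the negative controls was 2.44, 1.88, 1.59 and 3.96 on the same arrays. The scale thus follows background, and the counts under it hold shifts of whole arrays.

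The miR-17/miR-92 list was the 1 list that passed camera, as lower at 72 h (14 tested, median -0.13, adjusted p = 0.0271). It did not pass with an estimated correlation (adjusted p = 0.709), under normexp (adjusted p = 0.551), with scaling over all probes (adjusted p = 0.329) or with total gene signal (adjusted p = 0.0514), and 0 members passed over all miRNAs or when adjusted over the list alone. In both lines, 7 members were lower and 2 higher. miR-19b was at -0.71 (SE 0.24, adjusted p = 0.447), miR-17* at -0.61 (SE 0.09, adjusted p = 0.195), miR-18b at -0.37, miR-92a at -0.30 and miR-18a at -0.24, while miR-106b at 0.39 and miR-25 at 0.24 were higher in both lines. The other 6 lay between -0.14 and 0.05. Under normexp miR-92a, miR-17 and miR-20a stood at 0.12, 0.10 and 0.33 relative to the shift of all miRNAs, which was -0.34.

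Other lists gave values without a call. Under normexp alone 5 were called higher: let-7, miR-15/16, miR-23/24/27 and DNA damage (adjusted p = 0.0258 each) and p53-responsive (adjusted p = 0.0428). None was called there with an estimated correlation (adjusted p = 0.522 each). In the miR-15/16 family miR-16 was at 0.45 and miR-15a at 0.41, and 2 of 4 passed when adjusted over the list alone. Both tested miR-181 members passed when adjusted over the list alone, as did 1 of 5 in the miR-30 family, miR-30d (0.40, beside miR-30c at 0.21), and 1 of 6 in the DNA damage list. The p53-responsive list (5 tested, median 0.36) was led by miR-34a, followed by miR-192 at 0.40. let-7 was led by let-7i (0.46) and let-7g (0.36), miR-200 by miR-429 (-0.62, with -0.30 in DLD-1 and -0.93 in KM12C) and miR-141 (0.35), miR-29 by miR-29c (-0.36, with -0.06 in DLD-1 and -0.67 in KM12C) and miR-29b (-0.10), and miR-23/24/27 by miR-23a (0.45) and miR-27a (0.36). miR-183 at 0.51 and miR-96 at 0.10 led the miR-183 cluster, and miR-183 and miR-92a the colorectal tumour list. The intestinal list was led by miR-192 and miR-10a (0.28). The 2 miR-221/miR-222 members had a median of 0.11 and the hypoxia miRNA was at -0.04. miR-107, named after its values were seen, was at 0.36. Median, mean and test did not share a sign for the colorectal tumour and DNA damage lists.

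Under normexp limma called 39 miRNAs over 72 h, 0 higher and 39 lower. Over the 77 miRNAs with probes detected on all 6 arrays, limma called 7. miR-181a (1.06), miR-181b (1.05), miR-197 (1.05) and miR-193b (0.91) rose under that filter, and miR-19b (-0.71), miR-17* (-0.61) and miR-940 (-0.74, named after its values were seen) fell. No library without drug at 72 h was analysed here, so drug and time in culture cannot be separated.

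**Figure D3:**
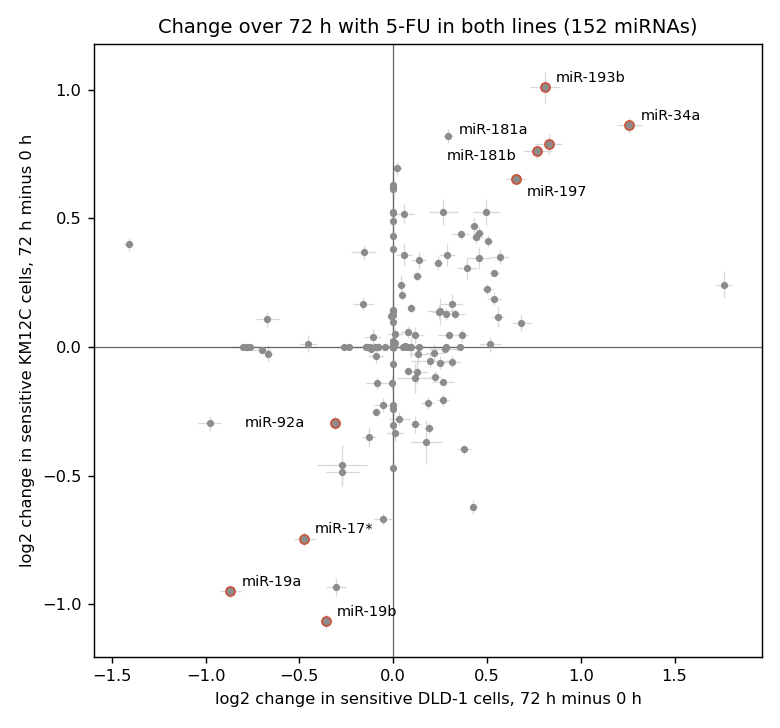
Log2 change between the 72 h and 0 h arrays in sensitive DLD-1 cells (horizontal axis) and sensitive KM12C cells (vertical axis); each of 152 points is 1 miRNA and bars are the standard error over spots, which is technical. Named in red are the 6 miRNAs at least 1.5-fold apart the same way in both lines, with miR-34a at 1.26 and 0.86, and 3 further miR-17/miR-92 members, of which miR-92a is at 0.12 under normexp once the shift of all miRNAs (-0.34) is removed.

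Agreement between the lines differed by contrast. Across 152 miRNAs, which are not independent replicates, the 72 h differences of DLD-1 and KM12C correlated at r = 0.414 (rho = 0.397), and 63 of the 91 miRNAs that moved in both lines had the same sign. The differences between resistant and sensitive cells correlated at r = 0.0629 (rho = 0.113), with the same sign in 50 of 91. The difference between these 2 correlations was not tested. Scaling over all probes turned the 72 h value to -0.261. Resistance in one line and 72 h of drug in the other share no array, and correlated at 0.0721 and 0.0295. Within a line both contrasts share the sensitive 0 h array, which alone gives 0.494 in simulation, with a covariance of 0.0300. The observed values were 0.391 in DLD-1 (covariance 0.0319) and 0.170 in KM12C (covariance 0.0157).

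The library with conflicting time labels, minus the DLD-1 resistant 0 h array, correlated with the 72 h difference of sensitive DLD-1 at r = 0.448 (rho = 0.449) and with that of KM12C at -0.124. Each pair sets a brighter array against a dimmer one, with 75th percentiles of 369.0 against 150.0, 300.9 against 122.9, and 420.7 against 273.5. Whether time or brightness underlies the r of 0.448 was not tested. Between the library with conflicting time labels and the DLD-1 resistant 0 h array, miR-34a was at the floor on both, miR-193b differed by 0.0082, miR-181a by 0.29, miR-19a by 0.13 and miR-19b by 0.51. The library labelled DLD-1 resistant 72 h, set against the same array, had miR-34a at 1.77, miR-193b at 1.15 and miR-19b at 0.04, a pair that stands across the line levels given above.

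The array files place the miR-19b target on chromosome 13 at 90801503 to 90801522 and miR-19a at 90801196 to 90801216, both inside the primary transcript of the host gene MIR17HG. They place miR-34a on chromosome 1 at 9134381 to 9134399, miR-193b on chromosome 16 at 14305381 to 14305396 and miR-10a on chromosome 17 at 44012265 to 44012284. miR-192 is placed on chromosome 11 at 64415251 to 64415269, and miR-215 on chromosome 1 at 218357881 to 218357901, beside miR-194 at 218358171 to 218358185. miR-30d lies on chromosome 8 at 135886344 to 135886357 and miR-30b at 135881995 to 135882011. The genome build of these positions is not given in the sources used here.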

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

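The tests of a wrong line label, a mixture and a drug response in the first pattern were chosen after the result was seen.

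The library labelled DLD-1 resistant 72 h stood out as data outside the 3 contrasts with the signature of the other line: 24 of the 27 miRNAs called between lines lay nearer the KM12C mean. A mixture of DLD-1 and KM12C RNA is argued against by miR-10a, whose level leaves room for at most 0.993% of DLD-1 RNA, even against the lowest library of each line. A label that names another line than the RNA may explain the levels, and the design text has a KM12C resistant 72 h sample that no label names. It remains a hypothesis, since the count of 24 and the correlations given next describe the observation itself. No test apart from these levels was made. A response of resistant DLD-1 cells to 5-FU is argued against as the whole cause by all 152 miRNAs. The library correlated with KM12C arrays at 0.972 to 0.983, as these did among themselves (0.972 to 0.986), and with DLD-1 arrays at 0.804 to 0.822. Sensitive DLD-1 cells after 72 h of drug still correlated with their 0 h array at 0.9735. A smaller part for the drug stays open, since no library of that group with undisputed labels was analysed. The library with conflicting time labels had a median position of 0.0364 on a scale from 0 (DLD-1) to 1 (KM12C), which decides nothing while its time is unknown.

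ebv-miR-BART13, one of the viral miRNAs kept as background, stood out as a signal outside the planned comparisons: it was above background on 4 libraries and on none of the 4 libraries labelled 0 h throughout. Its level was -1.96 in DLD-1 sensitive 72 h, -2.86 in the library with conflicting time labels, -3.48 in KM12C sensitive 72 h and at the floor of -3.72 in the library labelled DLD-1 resistant 72 h. These were also the brightest arrays, with a 75th percentile of 300.9 to 569.8 against 122.9 to 277.7 on the others. The viral ebv-miR-BHRF1-1, ebv-miR-BART17-3p, kshv-miR-K12-3 and hsv1-miR-LAT were above background only among the same libraries. Time and array brightness cannot be told apart here.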

How the results depend on the processing

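No paired analysis was possible because no replicate numbers tie arrays together beyond the cell line, which the fit holds as a term. Slide as a block was not run, since all arrays lie on 1 slide. The deposited table of processed values equals total gene signal, so it has no separate value. The fit on the arrays of 1 comparison and the fit without line do not apply to the contrast between lines. In leave-one-out fits a lone sample is assumed to vary like the other groups. Signal over background limits every value below the floor of log2 -3.72, set by the DLD-1 sensitive 0 h array, and miRNAs at the floor have an artificially small spread (miR-886-3p, miR-10a* and miR-149 in KM12C, miR-194, miR-215 and let-7e in DLD-1). The DLD-1 sensitive 0 h array detected the fewest miRNAs and enters both DLD-1 differences. Cyclic loess, the lowest floor, leaving out miRNAs at the floor throughout, and list tests under all scalings but quantile normalization (with either correlation) were chosen after seeing the data.

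For resistance, 0 miRNAs were called under every alternative except scaling to the median of detected probes, with 1 (miR-221, lower). Over 72 h, calls against 0 were 39 (0 higher, 39 lower) under normexp, 1 with the median of detected probes (miR-221, lower at -0.28), 7 (4 higher, 3 lower) over probes detected on all 6 arrays, 1 with the library with conflicting time labels as 0 h (miR-193b, higher) and 2 with the lowest floor (ebv-miR-BART13 and miR-181b, higher). Between lines, calls against 27 (13 higher, 14 lower) were 102 (13 higher, 89 lower) under normexp, 4 (2 and 2) with scaling over all probes, 46 (19 and 27) over probes detected on all 6 arrays, 2 (0 and 2) without a filter and 73 (36 and 37) with total gene signal. They were 44 (20 and 24) with the library with conflicting time labels as 0 h, 0 with the library labelled DLD-1 resistant 72 h, 74 (32 and 42) with the lowest floor, 43 (17 and 26) without miRNAs at the floor and 42 (24 and 18) after cyclic loess. Quantile normalization (14 higher, 11 lower), the brightest probe and an intensity trend each gave 25, robust variance 19, the median of detected probes 18 (7 higher, 11 lower) and the library with conflicting time labels as 72 h 40. Leaving out 1 library gave 4 to 17 between lines, 0 to 1 over 72 h (ebv-miR-BART13) and 0 to 0 for resistance. List tests called 0 in place of 2 with an estimated correlation and the same 2 after quantile normalization and with the median of detected probes. They called 9 under normexp, without either of the 2, and 4 after cyclic loess, with both. Scaling over all probes gave 2, both the p53-responsive list and neither of the first 2, and total gene signal 3, with the miR-30 family. All but quantile normalization, where it was not tried, called 0 with an estimated correlation. The 72 h correlation between lines became -0.261 with scaling over all probes. The same scaling gave 82 miRNAs past 1.5-fold for resistance in DLD-1 (5 otherwise), and 50 (17) in DLD-1 and 109 (16) in KM12C over 72 h. Under normexp the prior degrees of freedom were 273 and the median difference of all miRNAs was -0.34 over 72 h and -0.43 between lines. Under scaling over all probes it was 0.41 for resistance, -0.36 over 72 h and 0.47 between lines. Single miRNAs below are relative to these medians. The normexp offset of 50 was added before scaling, so dim miRNAs read lower on brighter arrays. Its one-sided counts and its list calls cannot be told apart from that shift. The scale over all probes lies among undetected probes and so follows background. Counts past 1.5-fold under it hold shifts of whole arrays. Fewer tested miRNAs or added samples explain other counts only in part. The prior degrees of freedom also differed, from 0.502 in the main fit. They were 27.5 over probes detected on all 6 arrays, 5.34 with the lowest floor, 1.58 without miRNAs at the floor and 0.0772 without a filter. Counts did not follow them throughout: scaling over all probes, among others, had a higher value than the main fit and fewer calls between lines. The main fit thus moderated variances little, also behind its 0 calls over 72 h and for resistance. Beyond these points the cause was not tested.

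These miRNAs changed sign, and the cause was not tested. Under normexp, for resistance: miR-93 -0.017, miR-18a -0.048 and miR-30e* -0.068. Over 72 h: miR-92a 0.12, miR-17 0.10, miR-20a 0.33, miR-29b 0.25, miR-923 0.011 and miR-221 0.061. Between lines: miR-92a 0.16, miR-17 0.13, miR-25 0.19, miR-17* 0.14, miR-18a 0.011 and miR-96 0.086. With scaling over all probes, for resistance: miR-17* 0.0041, miR-92a 0.12, miR-19b 0.078, miR-18b 0.086, miR-20a 0.20, miR-200a 0.021, miR-16 0.054, miR-29c 0.16, miR-29b 0.19, miR-30e* -0.16, miR-30d 0.090, miR-27a 0.093, miR-23a 0.14 and miR-221 0.11. Over 72 h: miR-93 -0.062, miR-192 -0.022, miR-30c -0.30 and miR-96 -0.12. Between lines: miR-17 0.095, miR-25 0.14, miR-19a 0.22, miR-17* 0.27, miR-18a 0.27 and miR-96 0.26. After quantile normalization, for resistance: miR-20a 0.0021 and miR-23a 0.0077. Over 72 h: miR-96 -0.013. Between lines: miR-18a 0.073. With the median of detected probes, for resistance: miR-93 -0.053, miR-106b -0.026 and miR-18a -0.024. Over 72 h: miR-93 -0.054 and miR-96 -0.021. With the brightest probe, for resistance: miR-29b 0.00080. Over 72 h: miR-20a 0.0029 and miR-29b 0.020. With total gene signal, for resistance: miR-18b 0.15, miR-20a 0.033 and miR-29b 0.066. Over 72 h: miR-93 -0.020 and miR-96 -0.051. With the library with conflicting time labels as 72 h, for resistance: miR-25 -0.082, miR-93 -0.063, miR-20b 0.027, miR-19b 0.25, miR-18b 0.11, miR-20a 0.12, miR-200a 0.093, miR-29c 0.23, miR-29b 0.18 and miR-21 0.024. Over 72 h: miR-25 -0.011, miR-93 -0.071, miR-20b 0.084, miR-20a 0.16 and miR-29b 0.15. With the same library as 0 h, for resistance: miR-93 -0.024, miR-20b 0.0073, miR-20a 0.078, miR-200a 0.023, miR-29c 0.059, miR-29b 0.10, miR-30d 0.05 and miR-27a 0.0042. With the library labelled DLD-1 resistant 72 h, for resistance: miR-93 -0.25, miR-19b 0.072, miR-215 0.78, miR-194 0.39, miR-98 -0.0096, miR-200a 0.11, miR-30d 0.54, miR-183 -0.25, miR-192 0.89, miR-10a -1.75 and miR-196b -0.60. Over 72 h: miR-93 -0.26, miR-183 -0.031, miR-10a -1.86 and miR-923 0.24. After cyclic loess, for resistance: miR-93 -0.062 and miR-106b -0.011. Over 72 h: miR-93 -0.023 and miR-20b 0.0019. Between lines: miR-17* 0.13, miR-18a 0.12 and miR-96 0.19.

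Leave-one-out ranges that crossed 0 for resistance were miR-106b -0.087 to 0.32, miR-183 -0.013 to 0.60, miR-18a -0.055 to 0.16, miR-18b -0.29 to 0.12, miR-194 -1.30 to 0.12, miR-19a -0.73 to 0.078, miR-19b -0.39 to 0.029, miR-200a -0.63 to 0.15, miR-20a -0.28 to 0.17, miR-20a* -0.20 to 0.014, miR-20b -0.15 to 0.026, miR-215 -1.37 to 0.10, miR-221 -0.13 to 0.024, miR-27a -0.45 to 0.11, miR-29b -0.37 to 0.23, miR-29c -0.28 to 0.084, miR-30e* -0.010 to 0.23, miR-92a -0.31 to 0.027 and miR-93 -0.0038 to 0.12. Over 72 h they were miR-20a -0.24 to 0.21, miR-20b -0.10 to 0.083, miR-27a -0.035 to 0.75, miR-29b -0.64 to 0.45, miR-923 -1.21 to 0.19, miR-93 -0.012 to 0.11 and miR-96 -0.052 to 0.25. Between lines they were miR-17* -0.13 to 0.0083, miR-18a -0.10 to 0.061, miR-18b -0.043 to 0.21 and miR-96 -0.17 to 0.014. For resistance, some of these fits also draw on the 72 h arrays. A range can thus reach above 0 where neither line's resistant array was higher, as for miR-19b, miR-194 and miR-215. Of all values of the named miRNAs under the alternatives, 2433 kept their direction and side of the threshold, 183 no longer passed, 77 newly passed and 141 changed sign. miR-10a, miR-192 and miR-31 kept their direction between lines throughout.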

Other observations

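The tests of background and floor, time in culture, DLD-1 cells among KM12C and culture spread were chosen after the results were seen. The tests after cyclic loess and the count of splits were set out before, though cyclic loess itself was added after the data were seen.

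Lower miR-192, miR-194 and miR-215 in resistant KM12C cells, from clusters on chromosomes 11 and 1, differed together by 2.20-fold to 2.43-fold between 2 arrays. DLD-1 cells among the resistant KM12C cells are argued against by miR-10a, which allows at most 0.764% of DLD-1 RNA against a mean fall of 56.4%. A shift that depends on signal is argued against as the whole cause by cyclic loess, after which the mean difference was -1.35 (-1.20 before). Spread between cultures of one condition cannot be told apart from resistance, because 0 further libraries of the resistant KM12C 0 h group were analysed. That loss of these intestinal, p53-induced miRNAs goes with resistance in KM12C is a hypothesis that may be checked with further cultures.

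The 72 h differences that ran together in both lines were led by miR-34a, miR-193b, miR-181a and miR-181b upward and miR-19a downward. A shift that depends on signal, from the brighter 72 h arrays, is argued against as the whole cause by cyclic loess, after which r was 0.394. These 5 miRNAs stayed at least 1.5-fold apart in both lines, while miR-197 did not. Background noise under dim miRNAs is argued against by r of 0.516 over the 77 miRNAs with probes detected on all 6 arrays, which leave out miR-34a and miR-19a, so for these 2 it stays open. Time in culture cannot be told apart from the drug, because 0 untreated 72 h libraries were analysed, so a response to 5-FU may be proposed only as a hypothesis.

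Between the lines, 27 miRNAs were called in the real split of the 6 libraries, and the highest of the other splits called 8. One of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.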
